A study of Schizophyllum commune with 14 samples.

How the data were processed

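Transcripts were measured by RNA sequencing of poly(A) RNA in 14 libraries of a Schizophyllum commune H4-8 dikaryon at 5 stages of fruiting. Vegetative mycelium, stage 1 primordium, young fruiting body and fruiting body had 3 biological replicates each, and stage 2 primordium had 2, numbered 2 and 3. The kit (TruSeq RNA) gives unstranded libraries, so reads of a gene and of a transcript running against it were not told apart. The 3 vegetative mycelium libraries were read on 1 flow cell and the 11 fruiting libraries on another.

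The per-library files were deposited with raw read counts for 16319 transcript models: unique gene reads (reads with 1 placement) and total gene reads (all placed reads). Unique reads came to between 13708387 and 24052213 per library, and reads with more than 1 placement were 0.59% to 0.89% of the total. The series table deposited by the authors holds log2 RPKM (reads scaled to transcript length and library total, here with a further factor per library) for 14681 of the 16319 models. Recomputed from the counts, that table rests on total reads: its spread around RPKM from total reads was 0.0009 to 0.001 on the log2 scale, and around RPKM from unique reads 0.5495 to 0.6719, over models with at least 200 total reads. That spread is around a separate offset for each library. The median offset from total-read RPKM ran from -0.273 in vegetative mycelium replicate 2 to 0.863 in stage 2 primordium replicate 2. Those libraries had the highest and lowest TMM scaling factors in the fit described below, 1.214 and 0.548. The table thus appears to hold RPKM with a similar scaling. Of the 1638 models outside it, 96.6% had at most 10 total reads in every library. The RPKM column of the per-library files is 0 throughout and was not used here. The submitters name R 3.0.2, edgeR 3.4.2 and limma 3.18.13 without saying what each did. The aligner, the counting method and the genome build are not given in the sources used here.

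Transcript IDs carry a number, and the gene reference gives locus tags and 42 symbols, with no product descriptions and no named chromosomes, so no positions are given. IDs below 2000000 were matched to locus tags of the same number (2004 of 2065). IDs from 2000000 up were matched after adding 287 to the locus tag number (14009 of 14254), an offset found from the files themselves: of 4001 offsets tried, the next best gave 1180 matches. In all 16013 matched pairs the transcript was no longer than the gene's span, and in 2188 it was equally long. Without an offset there were 1041 chance matches, of which 60.23% met that condition. A further 11 IDs matched by an older locus tag, SC6 among them, which makes its identity less certain, and 295 did not match. Symbols fell to 20 IDs.

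Unique reads were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by stage (14302 genes kept), TMM scaling, and a robust quasi-likelihood fit of stage over all 14 libraries. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, and calls of at least 4-fold were counted beside it. Tests were two-sided. Levels are means and SD of CPM (unique reads scaled to TMM-adjusted library totals). A difference between stages is a log2 fold change with a standard error (SE). The SE was taken as the size of the change over the square root of the F statistic of its quasi-likelihood test. The comparisons were stage 1 primordium against vegetative mycelium, each later stage against the stage before it, fruiting body against stage 1 primordium, and any difference among the 4 fruiting stages. A further count without a test took genes of the authors' table whose highest fruiting stage mean was above 4 RPKM and at least 4-fold above the lowest, with 0.01 RPKM added. The comparisons, tests, thresholds and most alternatives were chosen before the data were examined. Tested on simulated data with 100 changed genes per fold size and the same library numbers, the fit recovered 78% of 4-fold and 10% of 2-fold changes for stage 1 primordium against vegetative mycelium (14106 genes). It recovered 71% and 13% for stage 2 against stage 1 primordium (14141 genes), and 77% and 15% for fruiting body against young fruiting body (14124 genes). Of the 91, 86 and 96 calls made there, 3, 2 and 4 were genes that had not been changed. Apart from the changed genes, the simulated libraries shared a single mean and a single spread per gene, with no TMM factors. The real stages differed in spread and in many more genes, so these rates need not hold for them.

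Keyword lists of gene families had been planned, but they could not be applied without product descriptions. Lists were made from the symbols instead, before the levels of these genes were examined: 7 hydrophobins, 6 transcriptional regulators of fruiting, 4 genes of the mating type B locus and 3 other named genes. These lists hold only genes with a matched symbol and are not whole families. Further hydrophobins and regulators that the plan named had no matched symbol and are not covered. Lists of at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the lists within a comparison, with an estimated correlation beside it. The rule for named genes, fixed in advance, named regulators and hydrophobins of fruiting by symbol and, without product descriptions, the 2 IDs with the highest and the 2 with the lowest fold change. It was widened to all 20 symbols before their levels were examined. Such IDs had to be called, reach a mean of 10 CPM in a compared stage and have libraries that do not overlap between the stages.

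A single read corresponds to 0.0416 to 0.0729 CPM before TMM scaling. Where a stage had 0 reads, the fold is a lower bound against 3 reads over the stage, and with 1 to 3 reads it is a ratio with a 95% exact counting interval. Floors and intervals cover counting error only. Among the 20 symbol genes, bbp2 was too low to be tested. Of the other named genes, the share of reads with more than 1 placement was highest in SCHCODRAFT_02627923, at 3.73%.

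Alternatives were DESeq2 1.42.0 size factors or test, limma-voom, total reads, no filter on low counts, a replicate block, fits of only the compared stages, an adjusted p below 0.01, and leaving out each library in turn. For the RPKM count they were another pseudocount, no minimum and RPKM from total reads. After the data were seen, 3 more were added: no scaling factor beyond the library total, voom with library weights, and leaving out both stage 1 primordium replicate 3 and stage 2 primordium replicate 2. Stage 2 primordium replicate 1 is not analysed here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.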

Results

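The data follow fruiting body formation in the split gill mushroom Schizophyllum commune, in 14 RNA libraries from 5 stages of a dikaryon. Cultures were started from a 5 mm agar plug, kept in the dark at 30 °C for 5 days, then moved to 25 °C with 12 hours of light a day for 10 days. Stage 1 primordia were up to 2 mm high, stage 2 primordia 3 to 4 mm and young fruiting bodies 5 to 7 mm, and fruiting bodies were fully expanded. Unique reads numbered 17638722, 20148678 and 19355777 in replicates 1 to 3 of vegetative mycelium and 18469347, 18805939 and 19176833 in those of stage 1 primordium. Stage 2 primordium replicates 2 and 3 had 15694621 and 17842961, young fruiting body 17647012, 15777814 and 13708387, and fruiting body 24052213, 15717469 and 22977409.

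The first principal component of log2 CPM carried 47.2% of the variance and set the mycelium libraries, at -138.9 to -130.5, apart from all fruiting libraries, at -11.8 to 64.5. The second carried 23.3% and placed the stage 1 primordia between -100.9 and -64.5, below every other library. The spread between replicates differed by stage: the biological coefficient of variation was 0.092 in vegetative mycelium, 0.285 in stage 1 primordium, 0.455 in stage 2 primordium, 0.356 in young fruiting body and 0.342 in fruiting body. Stage 2 primordium replicate 2 had a TMM factor of 0.548, against 0.86 to 1.214 in the other libraries, 31.48% of its reads in its 50 most abundant genes, and 1874 models at 0 reads.

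**Figure D1:**
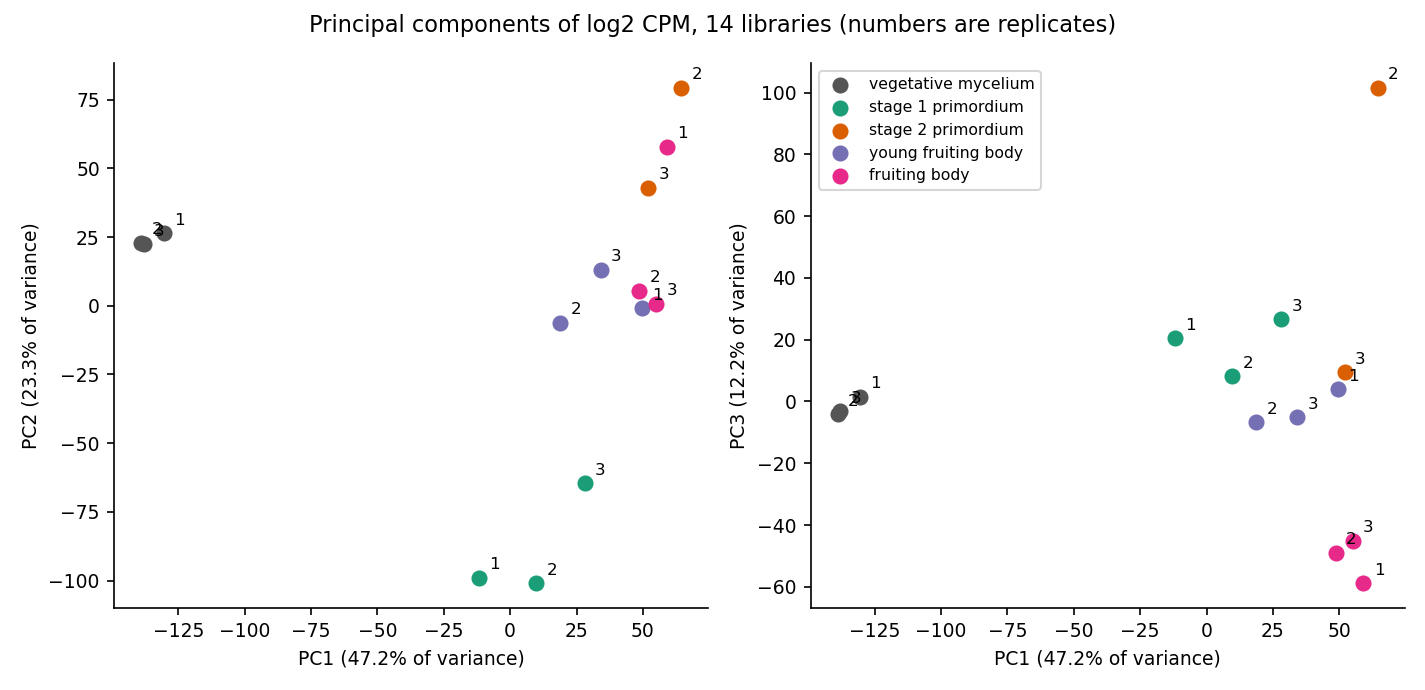
Principal components of log2 CPM, each point a library, coloured by stage and numbered by replicate (VM, vegetative mycelium; P1, stage 1 primordium; P2, stage 2 primordium; YFB, young fruiting body; FB, fruiting body); axes are component scores with the percent of variance. The mycelium libraries sit between -138.9 and -130.5 on the first component, and P2 replicate 2 is highest on the third, at 101.6.

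Stage 1 primordium against vegetative mycelium asked which transcripts accompany the start of fruiting. Hydrophobins, small secreted proteins that coat fungal surfaces, had higher means in the primordia for all 7 members with a symbol, in all alternatives tried, and 5 rose. Hyd8 rose from 0.198 ± 0.149 to 348 ± 316 CPM (SD, n = 3 each; log2 change 10.77 ± 1.41 SE, adjusted p = 8.21e-05), and SC6, a hydrophobin of fruiting dikaryons, from 0.458 ± 0.284 to 233 ± 169 CPM (8.98 ± 1.62, adjusted p = 0.000826). Among the 6 regulators, the zinc finger gene c2h2, needed for primordium formation, rose from 25.2 ± 2.44 to 256 ± 107 CPM (3.34 ± 0.55, adjusted p = 0.000346). Gat1, a GATA-type zinc finger regulator, fell from 326 ± 40.4 to 102 ± 23.7 CPM (-1.68 ± 0.24, adjusted p = 0.000108). The pheromone receptor gene bar3 and the pheromone precursor gene bbp2-1 of the mating type B locus rose too, by 1.39 ± 0.34 and 1.43 ± 0.23 (adjusted p = 0.00476 and 0.000267), while the precursor gene bbp2-6 was not called (0.05 ± 0.60, adjusted p = 0.952).

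In each of the called genes just named all 3 primordium libraries lay on 1 side of all 3 mycelium libraries. Hyd4 rose by 6.50 ± 1.17 (adjusted p = 0.000832). Hyd3 had 3 reads in all of vegetative mycelium, a ratio of 761 (95% exact counting interval 260 to 3690; adjusted p = 0.0115), and Hyd9 had 0, so it was at least 69.4-fold higher (adjusted p = 0.00908). Hyd3 was at 90.9 CPM in stage 1 primordium replicate 2 and at 1.69 and 0.243 CPM in the others, and without that library the ratio was 23.0 (7.24 to 117; log2 change 4.28, adjusted p = 0.102). Without it the log2 changes of Hyd4, Hyd8 and SC6 were 4.21, 9.72 and 8.20. Without 1 mycelium library the Hyd3 ratio was 489 to 1590 and the Hyd9 bound 44.6 to 48.3, and without stage 1 primordium replicate 3 the Hyd9 bound was 32.6. SC3, the hydrophobin of aerial hyphae, was at 1570 ± 1140 against 230 ± 85.7 CPM (adjusted p = 0.0717), and Hyd5 at 22.9 ± 20.8 against 4.71 ± 0.369 CPM (adjusted p = 0.0506). Adjusted over the list alone, 7 of 7 hydrophobins passed. Their median log2 change was 8.90, or 6.50 with Hyd9 at its bound, and the list as a whole passed camera (adjusted p = 0.00087), though not with an estimated correlation (adjusted p = 0.0688 with an estimated correlation). Of the regulators 2 rose, c2h2 and Bri1, a gene with an ARID/BRIGHT domain (0.94 ± 0.25, adjusted p = 0.00832), and 1 fell. Fst3, Fst4 and the blue light receptor gene WC1 were not called, with log2 changes of 0.85 ± 0.39, 0.50 ± 0.28 and 0.33 ± 0.25, and the list did not pass camera (adjusted p = 0.281). EGC1 rose by 0.92 ± 0.25 (adjusted p = 0.00872), while CFS2 and the laccase gene Lcc2 were not called (1.32 ± 0.57 and 0.47 ± 0.52).

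The largest rises by ID were SCHCODRAFT_02624825, from 1.45 ± 0.994 to 6680 ± 3950 CPM, and SCHCODRAFT_02627923, from 0.972 ± 1.54 to 3800 ± 1180 CPM. The largest falls were SCHCODRAFT_02633361, from 85.8 ± 50.1 to 0.168 ± 0.0593 CPM, and SCHCODRAFT_02594195, from 550 ± 15.3 to 1.12 ± 0.829 CPM. Without mycelium replicate 1 the log2 changes of SCHCODRAFT_02624825 and SCHCODRAFT_02627923 were 12.88 and 15.35 (12.17 and 11.95 with it). That of SCHCODRAFT_02627923 was 11.35 without replicate 2, and that of SCHCODRAFT_02594195 was -9.74 without stage 1 primordium replicate 1 (-8.93 with it). In all, 6286 of 14302 genes were called, 3222 higher and 3064 lower, of which 1043 and 934 by at least 4-fold. The split depends on the scaling: 51.3% of the calls were higher with TMM and 32.1% with no scaling factor beyond the library total, which moves the median of all genes from 0.02 to -0.30 and ends the calls of Bri1 (0.62) and EGC1 (0.59). Every mycelium library came from the other flow cell, so the design does not separate stage from flow cell here. Of the 1977 genes at least 4-fold apart, 533 came back within 2-fold of the mycelium, with a called change, in stage 2 primordium or fruiting body. A flow cell difference by itself would not give such a return, but joined to an opposite stage change it could. For the other 1444 stage and flow cell cannot be told apart. Hyd5 stayed uncalled without 6 of the 14 libraries and was called without each of the others. DESeq2 did not call Hyd9 (adjusted p = 0.109) nor voom Hyd3 (6.10), and DESeq2 called SC3 and CFS2 (adjusted p = 0.0325 and 0.0337). SC3 was called without young fruiting body replicate 2 (adjusted p = 0.00626), Fst3 without fruiting body replicate 1 (adjusted p = 0.0212) and CFS2 without stage 1 primordium replicate 1 (adjusted p = 0.00759). Fitted on these 2 stages alone, SC3, Hyd5, Fst3 and Fst4 were called (adjusted p = 0.00828, 0.0271, 0.00775 and 0.0129), as they were by weighted voom.

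**Figure D2:**
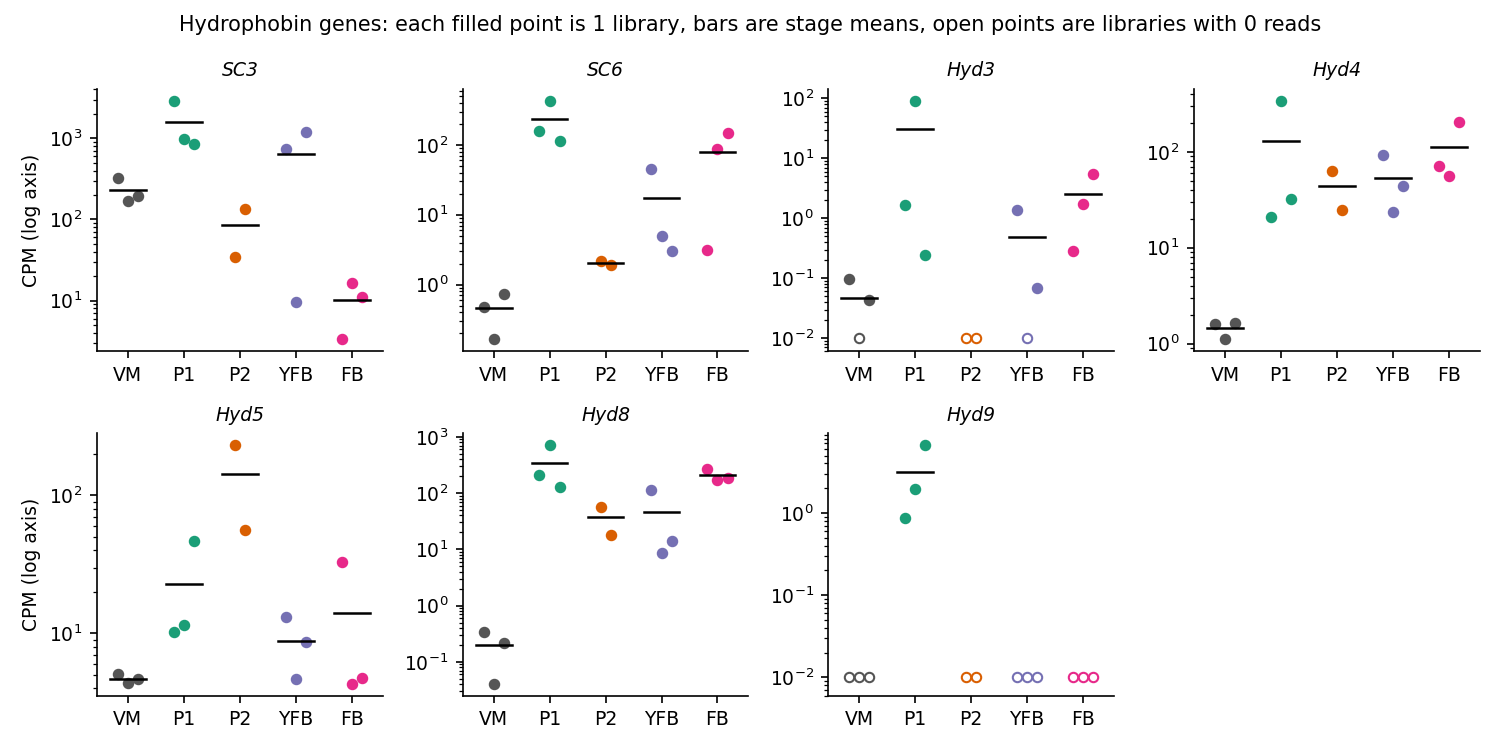
CPM (log axis) of the 7 hydrophobin genes by stage (VM, vegetative mycelium; P1, stage 1 primordium; P2, stage 2 primordium; YFB, young fruiting body; FB, fruiting body); each filled point is a library, bars are stage means, and open points at 0.01 CPM are libraries with 0 reads. Hyd8 lies between 127 and 710 CPM in the P1 libraries and at most at 0.337 CPM in the VM libraries.

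Stage 2 against stage 1 primordium asked what changes as primordia grow. WC1, the blue light receptor gene, rose from 84.5 ± 17.1 (SD, n = 3) to 268 ± 125 CPM (n = 2; log2 change 1.66 ± 0.27 SE, adjusted p = 0.000704). Of the other regulators 4 fell, the most c2h2, from 256 ± 107 to 34.9 ± 26.8 CPM (-2.87 ± 0.63, adjusted p = 0.00391), then Fst4 (-1.11 ± 0.33, adjusted p = 0.016), Gat1 (-0.85 ± 0.27, adjusted p = 0.0241) and Bri1 (-0.77 ± 0.29, adjusted p = 0.0434), whose call held under 8 of 25 alternatives and without 4 of the 14 libraries. Hydrophobins fell in 5 of 7 cases, with SC6 from 233 ± 169 to 2.07 ± 0.194 CPM (-6.82 ± 1.75, adjusted p = 0.0095) and SC3 from 1570 ± 1140 to 84.4 ± 71.1 CPM (-4.22 ± 1.48, adjusted p = 0.0382), while Hyd5 rose from 22.9 ± 20.8 to 144 ± 124 CPM (2.65 ± 0.92, adjusted p = 0.0359).

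In every called gene just named the 2 stage 2 libraries lay on 1 side of the 3 stage 1 libraries. Hyd8 fell by 3.23 (SE 1.13, adjusted p = 0.0382). Hyd3 and Hyd9 had 0 reads in stage 2 and were at least 274-fold and at least 25-fold lower (adjusted p = 0.0369 and 0.0311). The Hyd3 bound rests on stage 1 primordium replicate 2, at 90.9 CPM against 1.69 and 0.243 in the others, and without it was 8.27 (adjusted p = 0.157). Without 1 stage 2 library the bounds were 95.6 and 178 for Hyd3 and 8.72 and 16.2 for Hyd9, and without stage 1 primordium replicate 3 that of Hyd9 was 11.7. Hyd4, at 44.3 ± 27.4 against 131 ± 181 CPM, was not called (-1.57 ± 1.07), and neither was Fst3, at 263 ± 108 against 417 ± 113 CPM. Over the alternatives the log2 change of Hyd4 ran from -2.81 to 0.72, so its direction is not settled. The hydrophobins' median log2 change was -4.22, also with Hyd3 and Hyd9 at their bounds. Neither list passed camera (adjusted p = 0.0645 for hydrophobins and 0.131 for regulators; adjusted p = 0.328 and 0.399 with an estimated correlation). Without any 1 of stage 1 primordium replicates 1 and 3, stage 2 primordium replicate 2 and young fruiting body replicates 1 and 2 the hydrophobin list did pass (adjusted p between 0.0174 and 0.0469). CFS2 rose by 2.17 ± 0.60 (adjusted p = 0.0123), EGC1 fell by 1.22 (SE 0.29, adjusted p = 0.00529), bar3 fell by 1.09 (SE 0.39, adjusted p = 0.0381), and bbp2-1, bbp2-6 and Lcc2 were not called (-0.14 ± 0.26, -0.86 ± 0.85 and -1.37 ± 0.63).

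By ID, SCHCODRAFT_02507548 rose from 0.0809 ± 0.14 to 1210 ± 1710 CPM, with 3.12 CPM in 1 stage 2 library and 2420 in the other, and SCHCODRAFT_02513759 from 0.563 ± 0.27 to 1640 ± 2220 CPM (75.6 to 3210). SCHCODRAFT_02624825 fell from 6680 ± 3950 to 10.4 ± 10.8 CPM. SCHCODRAFT_02474010, at 10.3 ± 3.39 CPM in stage 1, had 1 read in stage 2, a ratio of 257 (95% exact counting interval 46.0 to 10200), 89.9 without stage 2 primordium replicate 3 and at least 55.8 without its replicate 2. In all, 5930 genes were called, 3172 higher and 2758 lower, of which 1119 and 495 by at least 4-fold. Of the calls 53.5% were higher with TMM and 32.6% with no scaling factor, which moves the median of all genes from 0.04 to -0.37 and ends the call of Hyd5 (2.09). The 2 stage 2 libraries differ widely, and without replicate 2 (TMM factor 0.548) 3069 genes were called, of which 2838 were among the 5930. Of the 18 named calls 13 ended without stage 2 primordium replicate 2 (c2h2 and WC1 held), 10 without its replicate 3, 8 without stage 1 primordium replicate 2, and 1 to 4 without its replicates 1 and 3, each mycelium library and young fruiting body replicates 1 and 3; WC1, c2h2 and SCHCODRAFT_02474010 held under all 25 alternatives. Without stage 2 primordium replicates 2 and 3 in turn the log2 changes were -2.26 and -3.96 for c2h2, 2.76 and 1.11 for CFS2, and 1.29 and 3.39 for Hyd5. They were -4.28 and -2.58 for Hyd8, and -3.55 and -5.47 for SC3. They were 5.27 and 14.92 for SCHCODRAFT_02507548 (13.86 with all libraries), 7.06 and 12.53 for SCHCODRAFT_02513759 (11.51), and -11.25 and -8.48 for SCHCODRAFT_02624825 (-9.35). Without stage 1 primordium replicate 2 they were -2.17 for Hyd8, 2.94 for CFS2 and -6.04 for SC6. Without its replicate 3 they were 3.76 for Hyd5 and 17.54 for SCHCODRAFT_02507548, and without its replicate 1 -3.43 for SC3. DESeq2 did not call Hyd9 (adjusted p = 0.224), nor voom Hyd3, Bri1, bar3 and SCHCODRAFT_02507548 (adjusted p between 0.0506 and 0.14). Fitted on these 2 stages alone, the calls of CFS2 (adjusted p = 0.0925), Fst4 (0.0555), Gat1 (0.0641), Hyd5 (0.0653), Hyd8 (0.0515) and Hyd3 (0.13) ended, at log2 changes of 2.18, -1.10, -0.84, 2.65, -3.23 and -11.93. With a replicate block those of Hyd3, SC3, Bri1 and bar3 ended (adjusted p between 0.0533 and 0.0758), and with weighted voom those of Hyd3, Hyd8, Hyd9, SC6, Gat1, Bri1 and bar3 (adjusted p between 0.0547 and 0.518). Without both stage 2 primordium replicate 2 and stage 1 primordium replicate 3, most of the 18 ended. Lcc2 was called with no scaling factor (-1.74, adjusted p = 0.0435) and without young fruiting body replicate 1.

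**Figure D3:**
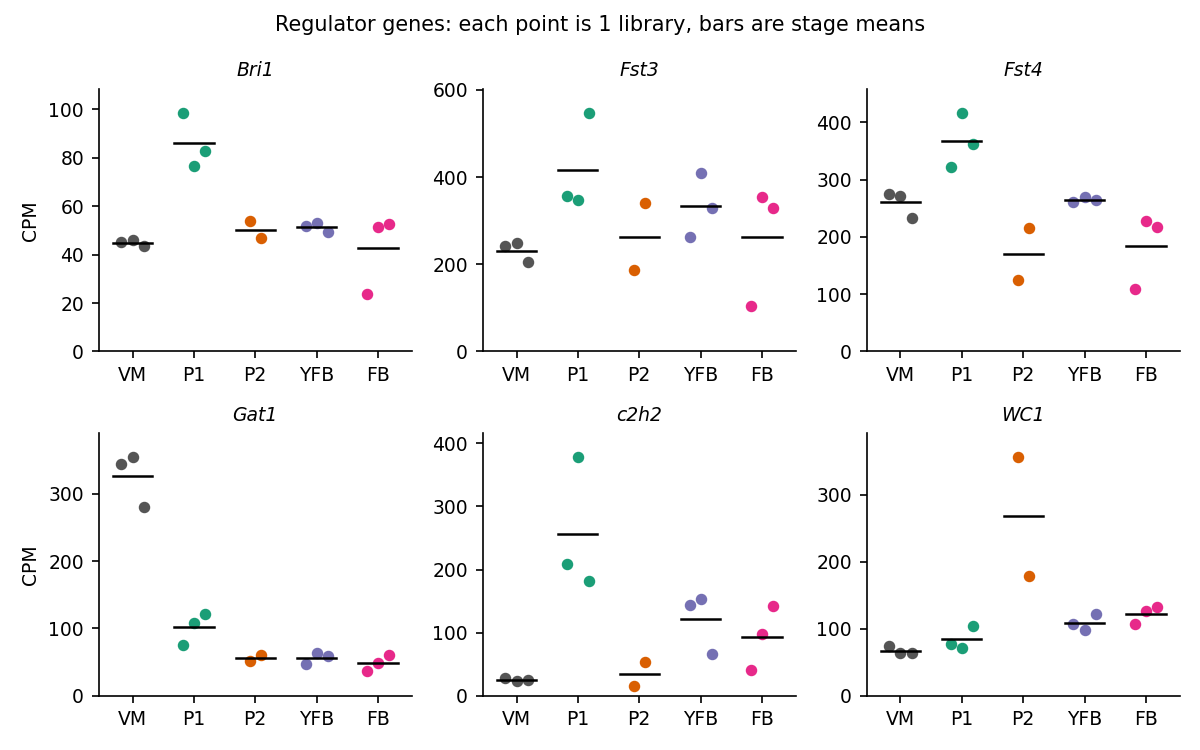
CPM of the 6 regulator genes by stage (VM, vegetative mycelium; P1, stage 1 primordium; P2, stage 2 primordium; YFB, young fruiting body; FB, fruiting body); each point is a library and bars are stage means. The P1 libraries hold c2h2 at 181 to 378 CPM, above the P2 libraries at 15.9 to 53.8, and WC1 at 71.7 to 104 CPM, below the P2 libraries at 179 to 356.

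Young fruiting body against stage 2 primordium asked what changes as the primordium opens into a small fruiting body. Hyd5 fell from 144 ± 124 (SD, n = 2) to 8.81 ± 4.22 CPM (n = 3; log2 change -4.02 ± 0.96 SE, adjusted p = 0.0314), the only call among the 7 hydrophobins. WC1 fell from 268 ± 125 to 109 ± 12.4 CPM (-1.30 ± 0.27, adjusted p = 0.0227), the only call among the 6 regulators. In both genes the 3 young fruiting body libraries lay below the 2 stage 2 libraries. The regulator c2h2 was at 121 ± 48.3 against 34.9 ± 26.8 CPM (1.79 ± 0.60, adjusted p = 0.0763), and passed when adjusted over the list alone (adjusted p = 0.0324). By ID, model 2630480 rose from 0.771 ± 0.761 to 30.9 ± 27.9 CPM and SCHCODRAFT_02636005 from 8.61 ± 1.49 to 151 ± 141 CPM. SCHCODRAFT_02497214 fell from 54.2 ± 75.2 to 0.676 ± 0.284 CPM and SCHCODRAFT_0107357 from 202 ± 251 to 3.29 ± 2.33 CPM. SCHCODRAFT_02497214 was at 107 CPM in 1 stage 2 library and 1.06 in the other, and its log2 change was -0.65 without stage 2 primordium replicate 2 (adjusted p = 0.873) against -6.32 with it.

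SC3, at 645 ± 593 against 84.4 ± 71.1 CPM, and SC6, at 17.6 ± 23.6 against 2.07 ± 0.194 CPM, were not called (adjusted p = 0.186 and 0.2). The median hydrophobin was higher in young fruiting body, at a log2 change of 1.16 with Hyd3 at its bound and Hyd9, with 0 reads in both stages, left out, whereas camera gave the list the lower direction (adjusted p = 0.796, the same as for the regulators). None of the mating type genes bbp2-1, bbp2-6 and bar3 or of CFS2, EGC1 and Lcc2 was called (log2 changes -0.37, 0.88, 0.10, 0.09, 0.37 and 0.56). In all, 1246 genes were called, 520 higher and 726 lower, of which 51 and 142 by at least 4-fold. The direction of this split depends on the scaling: 41.7% of the calls were higher with TMM and 87.8% with no scaling factor, which moves the median of all genes from 0.05 to 0.53 and ends the call of WC1 (-0.67). The calls depend on the other stages in the fit and on single libraries. Fitted on these 2 stages alone, edgeR called 0 genes (2139 at an unadjusted p below 0.05) and 6 of 6 named calls ended (adjusted p = 0.264 each), at log2 changes of -4.06 for Hyd5 and -1.32 for WC1. All 6 also ended with a replicate block (adjusted p between 0.0505 and 0.0766) and with weighted voom (0.125 to 0.38). EdgeR called 0 genes without stage 2 primordium replicate 2 too (1636 at an unadjusted p below 0.05), and 6 of 6 named calls ended. The log2 changes were then -2.67 for Hyd5, -0.71 for WC1, 4.55 for model 2630480 (5.15 with it) and -2.89 for SCHCODRAFT_0107357 (-5.93). Without stage 2 primordium replicate 3 they were -4.78 for Hyd5, 6.95 for model 2630480, -7.37 for SCHCODRAFT_02497214 and -6.87 for SCHCODRAFT_0107357. Without young fruiting body replicate 2 they were 3.07 for SCHCODRAFT_02636005 (4.13 with it) and -6.70 for SCHCODRAFT_0107357, and without replicate 3 4.29 for model 2630480. With all libraries DESeq2 called 2365, c2h2 among them (adjusted p = 0.0157), and voom 807, without model 2630480 and SCHCODRAFT_02497214 (adjusted p = 0.0821 and 0.188). Counts were 3621 without stage 2 primordium replicate 3, 155 without young fruiting body replicate 2, 1939 without fruiting body replicate 1, 783 and 799 without stage 1 primordium replicates 1 and 2, and 516, 478 and 557 without mycelium replicates 1, 2 and 3. Hyd5 was also not called without each mycelium library or young fruiting body replicates 2 and 3 (highest adjusted p 0.0876), nor WC1 without young fruiting body replicate 2 (adjusted p = 0.0632), and c2h2 was called without stage 2 primordium replicate 3 (adjusted p = 0.0186) or fruiting body replicate 1 (adjusted p = 0.045).

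Fruiting body against young fruiting body asked what accompanies the final expansion. SC3, the hydrophobin of aerial hyphae, fell from 645 ± 593 to 10.3 ± 6.58 CPM (SD, n = 3 each; log2 change -5.98 ± 1.35 SE, adjusted p = 0.0367), although 1 young fruiting body library, at 9.69 CPM, lay within the fruiting body range of 3.32 to 16.4. The other 6 hydrophobins were not called, with Hyd8 at 208 ± 50.7 against 45.3 ± 59.0 CPM (2.20 ± 0.92, adjusted p = 0.181) and SC6 at 79.8 ± 72.7 against 17.6 ± 23.6 CPM (2.18 ± 1.15, adjusted p = 0.283). Over the alternatives the log2 change ran from 1.71 to 4.21 for Hyd8 and from 1.38 to 4.31 for SC6. No regulator was called, and their log2 changes lay between -0.52 ± 0.28 (Fst4) and 0.17 ± 0.24 (WC1). By ID, SCHCODRAFT_02627376 rose from 4.08 ± 2.97 to 63.9 ± 48.4 CPM and SCHCODRAFT_02697331 from 991 ± 156 to 7630 ± 6870 CPM. Model 2630480 fell from 30.9 ± 27.9 to 1.23 ± 0.425 CPM and SCHCODRAFT_02742637 from 79.1 ± 64.6 to 4.00 ± 2.00 CPM. In these 4 IDs the libraries of the stages did not overlap, which the rule for naming IDs required.

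CFS2 was at 71.6 ± 24.6 against 31.2 ± 1.95 CPM and was not called (adjusted p = 0.206), nor were EGC1, Lcc2, bbp2-1, bbp2-6 and bar3 (log2 changes 0.26, 0.57, -0.04, 0.86 and 0.32). Neither list passed camera (adjusted p = 0.414 for hydrophobins and 0.213 for regulators). In all, 506 genes were called, 374 higher and 132 lower, of which 45 and 21 by at least 4-fold, and 73.9% of the calls were higher with TMM and 85.3% with no scaling factor (225 calls, without SC3). The calls depend on the other stages in the fit and on single libraries. Fitted on these 2 stages alone, edgeR called 0 genes (2253 at an unadjusted p below 0.05) and 5 of 5 named calls ended, SC3 at an adjusted p of 0.182, SCHCODRAFT_02627376 at 0.147, SCHCODRAFT_02697331 at 0.0876, model 2630480 at 0.107 and SCHCODRAFT_02742637 at 0.15. The log2 change of SC3 was then -5.98. With a replicate block all but model 2630480 ended (adjusted p between 0.06 and 0.0872), and with weighted voom SCHCODRAFT_02697331 did (0.0916), while Hyd8 and SC6 were called (adjusted p = 0.0248 and 0.0314). EdgeR called 0 genes without young fruiting body replicate 3 too (2859 at an unadjusted p below 0.05), and 5 of 5 named calls ended. The log2 changes themselves were then -5.20 for SC3 (adjusted p = 0.0958), 3.74 for SCHCODRAFT_02627376 (3.96 with it), 2.88 for SCHCODRAFT_02697331 (2.95), -3.77 for model 2630480 (-4.64) and -4.11 for SCHCODRAFT_02742637. Without young fruiting body replicate 1 that of SCHCODRAFT_02627376 was 4.75, and without fruiting body replicate 1 that of SCHCODRAFT_02697331 was 1.89 (adjusted p = 0.0993). With all libraries DESeq2 called 1351 and voom 495, without SC3, model 2630480 and SCHCODRAFT_02742637 (adjusted p between 0.0573 and 0.0891). Counts were 77 without young fruiting body replicate 2, 282 and 267 without fruiting body replicates 1 and 2, 238, 198 and 208 without mycelium replicates 1, 2 and 3, and 855 without either stage 2 primordium library. SC3 was also not called without each mycelium library or each fruiting body library (highest adjusted p 0.0909), and Hyd8 was called without young fruiting body replicate 1 (4.21, adjusted p = 0.0228).

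Fruiting body against stage 1 primordium spanned the whole of fruiting within 1 flow cell. SC3 fell from 1570 ± 1140 to 10.3 ± 6.58 CPM (SD, n = 3 each; log2 change -7.26 ± 1.43 SE, adjusted p = 0.00292), and CFS2 rose from 6.49 ± 5.07 to 71.6 ± 24.6 CPM (3.46 ± 0.58, adjusted p = 0.001). Of the 6 regulators 4 fell: Gat1 from 102 ± 23.7 to 48.2 ± 11.9 CPM (-1.08 ± 0.24, adjusted p = 0.00473), Bri1 (-1.01 ± 0.25, adjusted p = 0.00836), Fst4, which is needed for the switch to fruiting (-0.99 ± 0.28, adjusted p = 0.017), and c2h2 from 256 ± 107 to 93.8 ± 51 CPM (-1.45 ± 0.51, adjusted p = 0.0439). Fst3 and WC1 were not called (-0.67 ± 0.39 and 0.53 ± 0.25). By ID, SCHCODRAFT_02589830 rose from 0.713 ± 1.01 to 102 ± 121 CPM. SCHCODRAFT_02699043, at 16.7 ± 22.2 CPM, had 1 read in stage 1 primordium, a ratio of 995 (95% exact counting interval 178 to 39300). It was at 42.4 CPM in fruiting body replicate 1 and at 2.86 and 4.98 CPM in the others, and without that library the ratio was 224 (39.6 to 8880; log2 change 7.29 against 9.38, adjusted p = 0.00185). Without 1 stage 1 library the ratio was 638 and 660, or at least 231 where no read was left. SCHCODRAFT_02625127 fell from 405 ± 439 to 3.61 ± 0.476 CPM and model 2630480 from 71.7 ± 51.8 to 1.23 ± 0.425 CPM.

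In each called gene just named all 3 fruiting bodies lay on 1 side of all 3 primordia, which the naming rule required of the genes named by ID. Hyd9 had 0 reads in fruiting body and was at least 68.1-fold lower (adjusted p = 0.0138), with a bound of 32 without stage 1 primordium replicate 3 and of 42.7 to 50.8 without 1 fruiting body library. Without stage 1 primordium replicate 1 the log2 changes were -6.50 for SC3, -5.56 for SCHCODRAFT_02625127 (-6.81 with it) and -5.12 for model 2630480 (-5.86), and without its replicate 2 4.23 for CFS2. That of SCHCODRAFT_02589830 was 9.51 without stage 1 primordium replicate 3 and 5.55 without fruiting body replicate 1 (7.20 with all). The other 5 hydrophobins were not called, among them Hyd8 at 208 ± 50.7 against 348 ± 316 CPM and Hyd4 at 112 ± 82.7 against 131 ± 181 CPM. The hydrophobins' median log2 change was -1.55, also with Hyd9 at its bound. Both lists passed camera in the lower direction (adjusted p = 0.0263 each), and neither did with an estimated correlation (adjusted p = 0.209 each with an estimated correlation). The hydrophobin list also did not pass without stage 1 primordium replicate 2 (adjusted p = 0.136). EGC1, Lcc2, bbp2-1, bbp2-6 and bar3 were not called (log2 changes -0.60, -0.24, -0.55, 0.88 and -0.67). In all, 4853 genes were called, 2784 higher and 2069 lower, of which 902 and 203 by at least 4-fold. Of the calls 57.4% were higher with TMM and 75.8% with no scaling factor, which moves the median of all genes from 0.04 to 0.20 and ends the calls of Fst4 (-0.83) and c2h2 (-1.31). The c2h2 call also ended without any 1 of stage 1 primordium replicates 1 and 2, fruiting body replicates 1 and 2, young fruiting body replicate 1 and the mycelium libraries (highest adjusted p 0.166), in a fit of these 2 stages alone (adjusted p = 0.0559) and with a replicate block (adjusted p = 0.0659), and that of Fst4 without stage 1 primordium replicate 2 (adjusted p = 0.0607). Without that library Hyd4 was called higher (2.06, adjusted p = 0.0477), against -0.23 with it. Calls came up for Hyd3 without stage 1 primordium replicate 3, Hyd5 without fruiting body replicate 1, WC1 and EGC1 without either stage 2 primordium library, and bbp2-1 without young fruiting body replicate 3 (adjusted p between 0.0339 and 0.049). DESeq2 called EGC1 and bbp2-1 but not Hyd9 (adjusted p = 0.122), and WC1 was called with no scaling factor (0.71). Weighted voom called Hyd5, WC1, EGC1, bbp2-1 and bbp2-6 (adjusted p between 0.00272 and 0.0377), and without both stage 2 primordium replicate 2 and stage 1 primordium replicate 3 Hyd3 and WC1 were called (adjusted p = 0.049 and 0.0193).

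**Figure D4:**
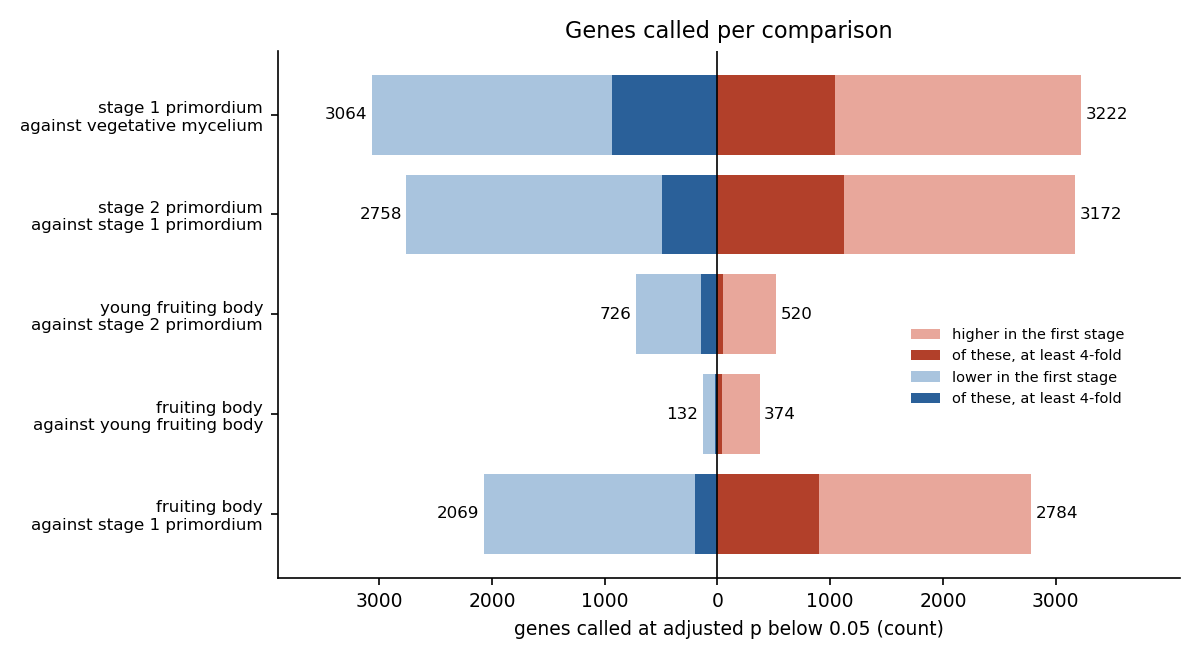
Genes called at an adjusted p below 0.05 in each comparison (counts); bars to the right are genes higher in the first stage, bars to the left genes lower, and the darker parts are calls of at least 4-fold. In each direction the longest bar is that of stage 1 primordium against vegetative mycelium, 3222 to the right and 3064 to the left, and with no scaling factor beyond the library total the share of higher genes moves by over 10 percentage points in every comparison.

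Any difference among the 4 fruiting stages was tested within the fit of all 14 libraries, and the stages tested, with 11 libraries, share 1 flow cell. Of the genes with a symbol WC1 (adjusted p = 0.00182), CFS2 (adjusted p = 0.00382), SC3 (adjusted p = 0.00612), Gat1 (adjusted p = 0.00868), Hyd5 (adjusted p = 0.00964) and c2h2 (adjusted p = 0.0112) passed most clearly, with largest log2 ranges between stages of 1.66, 3.46, 7.26, 1.08, 4.02 and 2.87. SC3, Gat1 and c2h2 had their highest mean in stage 1 primordium, WC1 and Hyd5 in stage 2 primordium, and CFS2 in fruiting body. Fitted on those 11 libraries alone, these genes passed at 0.00815, 0.0147, 0.0201, 0.025, 0.029 and 0.0308. Hyd5 did not pass without stage 2 primordium replicate 2 (adjusted p = 0.188), nor Gat1 and Hyd5 without both that library and stage 1 primordium replicate 3 (adjusted p = 0.0663 and 0.0999), and DESeq2 gave Hyd5 no adjusted p. Fst3 and Hyd4 did not pass (adjusted p = 0.378 and 0.399). In all, 6945 genes were called, of which 2167 spanned at least 4-fold. The fit of the 11 libraries alone called 4759, of which 4758 were among the 6945. Of the 6945, 2342 (33.7%) had their highest mean log CPM in stage 1 primordium, 2244 (32.3%) in stage 2 primordium, 216 (3.1%) in young fruiting body and 2143 (30.9%) in fruiting body. Of the 2167 that spanned at least 4-fold, these numbers were 495, 806, 59 and 807, so the order of the stages differs there. These counts of highest stages rest on TMM scaling. Their stage 2 primordium mean comes from 2 libraries, and replicate 2 of these had a TMM factor of 0.548. Whether they hold under another scaling or without that library is not shown here. By the authors' RPKM table, with no test, 1898 of 14681 genes were at least 4-fold apart between fruiting stages, and 2899 without stage 2 primordium replicate 3. Without both stage 2 primordium replicate 2 and stage 1 primordium replicate 3, 4524 genes were called.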

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

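The read minimums used in this part, and the test of the second group of models by total reads, were chosen only after the data were seen.

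SCHCODRAFT_02519496 lies outside the authors' table, yet vegetative mycelium replicate 1 had 247 total reads of it, and 4 libraries in all exceeded 3 reads. Absence from that table thus does not mean a count of 0. Of the models outside that table, 56 had more than 10 total reads in some library.

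Reads with more than 1 placement, which the comparisons leave out, made up at least 90% of the total reads of 56 models among the 11131 with at least 1000 total reads. By unique reads only 5 of these models were tested. By total reads all 56 were, and edgeR called 27 between stage 1 primordium and vegetative mycelium, 17 higher and 10 lower, and 16, 1, 2 and 17 in the other comparisons in the order given above. Several of these models come in pairs with near-equal totals, such as SCHCODRAFT_02613396 and SCHCODRAFT_02613420, with 20848 and 20843 total reads and 0 unique reads each. Such pairs may draw on the same reads, so these calls are not a count of independent genes.

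SCHCODRAFT_02646106 had the most such reads, 92217 of its 122307 total reads (75.4%) over all libraries, and its unique reads hold the rest.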

How the results depend on the processing

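No scaling factor, voom with library weights and leaving out both libraries apart from their stage were chosen only after the data were seen. Counts are in the order P1-VM, P2-P1, YFB-P2, FB-YFB, FB-P1 and any difference (VM, vegetative mycelium; P1 and P2, primordium stages; YFB and FB, young and full fruiting body), as reported 6286, 5930, 1246, 506, 4853 and 6945. Under the alternatives 122 counts stayed within 1.5 times, 32 were lower, 9 higher, and 1 RPKM count moved. An adjusted p below 0.01 left 3283 (P2-P1), 0 (YFB-P2), 1 (FB-YFB), 2427 (FB-P1) and 3450 (any). DESeq2 called 2365 (YFB-P2) and 1351 (FB-YFB), voom 807 (YFB-P2), and no scaling factor 225 (FB-YFB). Fitting only the compared stages gave 3939 (P2-P1), 0 (YFB-P2) and 0 (FB-YFB). Weighted voom gave 9743 (P1-VM), 3745 (P2-P1), 0 (YFB-P2) and 1339 (FB-YFB). Without both libraries apart from their stage edgeR called 3281 (P2-P1), 0 (YFB-P2), 986 (FB-YFB) and 4524 (any). At an unadjusted p below 0.05 the counts of 0 became, for YFB-P2, 4044 (stricter threshold), 2139 (compared stages), 1966 (weighted voom) and 1667 (both left out), and for FB-YFB 2253. Leaving out each library gave 4875 to 6917, 3069 to 6637, 0 to 3621, 0 to 855, 3252 to 5563 and 5033 to 8189, and 1472 to 2899 for the RPKM count (1898). Deviations from the stage means correlated no more strongly in the 26 same-numbered pairs (-0.258 to 0.231) than in the 52 others (-0.339 to 0.339). Deviations within a stage depend on each other, and those of the P2 libraries mirror each other. These values therefore cannot tell whether same-numbered libraries share a culture. A replicate block gave 5967, 5374, 201, 235, 4346 and 5882.

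For the hydrophobin list the adjusted p with an estimated correlation was 0.0688 (P1-VM) and 0.209 (FB-P1), and for the regulators 0.209 (FB-P1). At the preset correlation, without both libraries apart from their stage, it was 0.00982 for hydrophobins (P2-P1, 0.0645 as reported) and 0.0558 for regulators (FB-P1), and leaving out each library gave hydrophobins 0.0174 to 0.197 (P2-P1) and 0.012 to 0.136 (FB-P1). Among named genes 1355 alternatives kept a call and its direction, 236 lost a call, 52 gained one, and of those uncalled both ways 1494 kept the direction and 63 turned. Hyd4 (FB-P1) turned and was called, from -0.23 to 2.06 without P1 replicate 2 (range -1.03 to 2.06). A stricter threshold lowers counts by construction. The fit takes a single spread per gene over all stages. The biological coefficient of variation was 0.092 in vegetative mycelium, 0.285 in P1, 0.455 in P2, 0.356 in YFB and 0.342 in FB. Adjusted p values of every comparison among the fruiting stages thus rest in part on the lower spread of the mycelium. Besides YFB-P2 and FB-YFB, counts without 1 mycelium library fell to 5334 to 5395 (P2-P1), 4235 to 4271 (FB-P1) and 5887 to 5978 (any). Otherwise the cause was not tested. Without P2 replicate 2 or 3 its lone library is assumed to vary like the other stages.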

Other observations

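The gene lists by level in the next paragraphs, the tests for a mislabelled or mixed stage 1 primordium library, and the thinning to a TMM-scaled depth, were chosen only after the results were seen.

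SCHCODRAFT_02628901 rose from 14.2 ± 13.6 CPM in vegetative mycelium to 31900 ± 14600 CPM in stage 1 primordium (SD, n = 3 each; log2 change 11.13 ± 1.27 SE, adjusted p = 1.54e-05) and was at 40300 ± 19200 CPM in stage 2 primordium (n = 2). SCHCODRAFT_02372730 rose from 7.59 ± 12.6 to 28500 ± 2880 CPM (11.88 ± 1.97, adjusted p = 0.000432) and SCHCODRAFT_02625787 from 165 ± 113 to 17200 ± 11100 CPM (6.71 ± 0.79, adjusted p = 1.92e-05). SCHCODRAFT_02605614 rose from 3.14 ± 3.62 to 2710 ± 2770 CPM in stage 1 (9.75 ± 1.28, adjusted p = 6.04e-05) and was at 19700 ± 13400 CPM in stage 2 primordium. The most abundant transcript of the mycelium, SCHCODRAFT_02604446, fell from 7330 ± 1130 to 2050 ± 429 CPM in stage 1 primordium (-1.83 ± 0.32, adjusted p = 0.000421) and was at 4390 ± 594 CPM in stage 2. Of the next in the mycelium, SCHCODRAFT_02611788, at 6480 ± 555 against 4920 ± 574 CPM, was not called (-0.40 ± 0.31, adjusted p = 0.322), except in a fit of these 2 stages alone and by weighted voom (adjusted p = 0.0289 and 0.00685). SCHCODRAFT_02607677 fell from 6210 ± 917 to 758 ± 690 CPM (-3.03 ± 0.54, adjusted p = 0.000497; -4.12 without stage 1 primordium replicate 3). The 6 called changes between mycelium and stage 1 primordium held under all 25 alternatives. Without mycelium replicate 1 the log2 changes of SCHCODRAFT_02628901, SCHCODRAFT_02372730, SCHCODRAFT_02625787 and SCHCODRAFT_02605614 were 12.28, 16.44, 7.40 and 11.32, and without stage 1 primordium replicate 3 those of SCHCODRAFT_02625787 and SCHCODRAFT_02605614 were 6.04 and 8.49.

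Genes below 1 CPM in every mycelium library and at 10 CPM or more in every fruiting library numbered 18, of which 4 were at 100 CPM or more in all 11. SCHCODRAFT_02664662 had at most 0.626 CPM in the mycelium and 116 to 462 CPM in the fruiting libraries, and SCHCODRAFT_02624785 at most 0.963 and 127 to 270 CPM. The reverse held for 3 genes at 10 CPM and for 0 at 100 CPM: SCHCODRAFT_02633361 (37.6 CPM or more in the mycelium, at most 0.559 in fruiting), SCHCODRAFT_01109319 (26.2 and 0.728) and SCHCODRAFT_02504172 (10.1 and 0.82). These counts carry no test, and all mycelium libraries share a flow cell that no fruiting library has.

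That flow cell might account for differences from the mycelium. Of the 1977 genes at least 4-fold apart in stage 1 primordium, 533 (27%) came back within 2-fold of the mycelium with a called change in stage 2 primordium (386) or fruiting body (295), 242 that had been higher and 291 that had been lower. A difference between flow cells shifts all fruiting libraries, so by itself it would not give such a return. Joined to an opposite change between fruiting stages it could, and how often that happens was not tested. Both comparisons also use the same stage 1 primordium libraries. The return therefore does not settle, for any single gene of the 533, what set stage 1 primordium apart from the mycelium. For the other 1444, with a median log2 distance of 2.86 between fruiting body and mycelium, flow cell and stage cannot be told apart, since no mycelium library was read with the fruiting libraries.

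Stage 2 primordium replicate 2 lies apart from replicate 3. A lower read total is argued against as the whole cause: replicate 3 thinned to the same total had 1566 models at 0 reads (SD 5.3 over 20 thinnings), against 1874 in replicate 2. Thinned to the TMM-scaled depth of replicate 2, 0.537 of its own, it had 1711 (SD 12.7). A transcript length bias is argued against too, as the log ratio of the replicates correlated with length across 14302 transcripts at 0.081, and in the 12 other pairs of replicates at -0.274 to 0.206 (genes are not independent replicates). No few genes took most of the reads, as the top 50 held 31.48% (27.26% in replicate 3) and the top 10 13.8% (15.03%). A larger share in abundant genes may contribute and stays open: with its 50 most abundant genes removed everywhere, the TMM factor was 0.692 (SD 0.019 over 50 resamples) in place of 0.548, too near the 0.7 set as the limit to decide. No biological explanation was tested.

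Stage 1 primordium replicate 3 lies toward the later stages. A wrong label on a library of a later stage is argued against: on an axis from its stage mates at 0 to the later libraries at 1 it lay at 0.362, against 0.773 for the lowest of 8 later libraries, and it correlated at 0.967 and 0.97 with its mates and at most at 0.956 with a later library. Stage 1 tissue mixed with later tissue stays open. The 528 genes low in its mates gave a share of 9% (quartiles 5 to 20.6) and 73 genes low in later stages a share of 50.2% (21.7 to 72.8), which differ by -41.2 percentage points. The quartiles nearly meet, and the same difference was -4.9 and -15.1 points in replicates 1 and 2, where the shares from genes low in later stages had quartiles of -45.4 to 26.8 and -32.6 to 35.5. Progress of the whole primordium toward the next stage also remains a possible explanation and was not tested.

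Neighbouring genes may change together between mycelium and stage 1 primordium. Of 12870 adjacent pairs 357 were both at least 4-fold apart in the same direction, 2.91 times the 122.6 of shuffled orders (permutation p = 0.001, the smallest that 1000 shuffles can give). Among the 1742 pairs at least 1000 bases apart the ratio was 3.65. The shuffles drew on all genes and not only on genes beside such gaps, which may change more often. This ratio therefore cannot decide whether reads running over from a gene to its neighbour contribute. With 1 gene between the members of a pair the ratio was 1.63, and with 4 genes between them 1.23 (permutation p = 0.02). Copies of a gene that lie side by side were not tested and stay open.

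Genes at least 4-fold higher in stage 1 primordium had short transcripts, with a median of 1219 bases, against 1333 for the median of 10000 random lists matched on mean expression (95% of lists between 1271 and 1390). Genes at least 4-fold lower did not stand out, at 1110 bases (1062 to 1171). The link may come from families of small secreted proteins, which was not tested.

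Splits of the same 6 libraries into 3 and 3 are too few, at 10 with the real one, for a share under 0.05. Every other split also mixes both stages within each group, which widens the spread there. Few calls in the other splits are thus built in, and no conclusion is drawn from them. For stage 1 primordium against vegetative mycelium 1 of the 10 splits, the real one, gave as many as 6286 genes, and the highest other gave 0 in edgeR (at most 250 at an unadjusted p below 0.05). For fruiting body against young fruiting body it was also 1 of 10, with 506 genes and 126 in the highest other, and for fruiting body against stage 1 primordium 1 of 10, with 4853 and 0 (at most 1042 at an unadjusted p below 0.05). No other tool was run on the splits.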
